A study of Mus musculus with 10 samples.

How the data were processed

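Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in lineage-negative haematopoietic stem and progenitor cells (HSPCs) from mouse bone marrow. The 8 HSPC libraries come from 4 genotypes with 2 libraries each, namely wild type (WT), Npm1c, Flt3-ITD and the double mutant (DM) carrying both alleles. Groups and replicate numbers were taken from the sample titles. Another 2 samples, of WT neutrophils, were not analysed here.

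Reads were aligned with Bowtie2 and peaks were called with MACS2 on the mm10 build, per the submitters' processing notes, which as used here give no versions, thresholds or read filters. Whether reads were shifted for the Tn5 offset and whether duplicates were removed is not given in the sources used here. The deposited lists hold 3 columns per peak, the chromosome, start and end, and no header, height, fold enrichment or q value, so a peak is either present or absent in a library and has no strength beyond its width. Each list belongs to 1 library, per the labels, and none is pooled. The number of reads behind each list is not given in the sources used here, and a shorter list can come from fewer reads or from less open chromatin. Between 43825 and 80916 peaks were listed per library.

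Peaks on chromosomes 1 to 19 and X of the 8 libraries were merged wherever they shared at least 1 bp, which gave 103446 regions with a median width of 435 bp. A region was called in a library that had a peak in it. A region was gained in one genotype against another when it was called in both libraries of the first and in neither library of the second, and lost in the opposite case. Coordinates are counted from 1 on mm10. Genes came from a RefSeq gene table of the matching assembly, GRCm38.p6, with 21634 genes used, all protein-coding except 3 members of the gene lists. The table gives no strand or exons, so the planned distance to the transcription start site was replaced. A region went to the gene whose body held its midpoint, the shortest one where several did, and otherwise to the nearest gene end within 100 kb. Distances to genes, and whether a region lies inside a gene or near its end, refer to the midpoint unless an overlap is stated. This assigned 94.8% of regions, of which no exon, intron or UTR is stated. A planned test of transcription factor motifs needs the genome sequence and was not run.

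Gained and lost regions were counted for 5 comparisons. Each count was set against 1000 randomisations of the calls that kept the number of calls of every region and every library, and against the other ways of splitting the same 4 libraries 2 against 2, here called mixed splits. The randomisation treats all libraries as interchangeable, and mixed splits part the libraries of a genotype. Any likeness of the 2 libraries of a genotype, whatever its source, thus raises a count above the randomisation, and a p from it does not show an effect of genotype. A region compared between 2 libraries and 2 libraries cannot reach an exact two-sided p under 0.333, so no single region was tested in these comparisons. Between libraries with and without an allele, 4 against 4, a Fisher exact test per region can reach 0.0286. Library measures were compared with two-sided exact permutation tests over 70 relabellings. The similarity of libraries was the Jaccard index, the number of bases covered in both over the number covered in either, with a one-sided exact permutation test over all pairings of the libraries.

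The 16 gene lists, with 386 genes, were fixed before the data were examined, as were the tests, the named-gene rule and most of the alternative settings. They cover the HOX cluster and cofactors, haematopoietic stem cells, neutrophil granules, monocytes and macrophages, the erythroid, megakaryocyte and B-lymphoid lineages, T and NK cells, mast cells and basophils, dendritic cells, stroma and endothelium, JAK-STAT and FLT3 signalling, AP-1 and immediate early genes, the interferon response, haematopoietic transcription factors and housekeeping genes. All 386 genes were found in the gene table, and some genes belong to several lists. For each list, the number of gained or lost regions assigned to its genes was compared with 10000 random gene lists of the same size, matched on the number of regions per gene. The permutation p is one-sided (higher), with Benjamini-Hochberg adjustment over all lists and both directions of a comparison. The same test for fewer regions than in random lists, the tests of regions particular to DM or to an allele, a test of runs of regions within 20 kb, the test of the difference between allele effects, the share of each list in each library and a list of heat shock genes were all added after the data had been seen.

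The text names, per comparison, up to 4 genes per list and direction with most changed regions, the 5 widest gained and the 5 widest lost regions by their mean width percentile within the lists (the files hold no peak score), the 5 genes with most gained and the 5 with most lost regions, and Npm1, Flt3 and Mx1 in every library. Other genes are named as chosen after their values were seen. Ranks by number of changed regions favour genes with many regions, so the share of all regions changed is given for each comparison between genotypes.

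The count and list tests were checked on simulated calls for DM against WT with 103446 regions and 16620 genes. In 20 simulated matrices, 100% of 200 regions set as gained were counted, which the definition of a gained region gives by construction. Of 320 gene list tests without an effect, 3.75% gave a p under 0.05, and a set excess in the dendritic list was detected in 20. The simulated calls were shuffled without regard to position, so they do not hold the runs of neighbouring regions of the real lists. Alternatives changed the share of a region that a call needs, the merging distance, the sequences used, the rule for absence, the libraries, the distance to genes and the test of gene lists. Alternatives based on peak scores were not run, because the files hold none. Reducing every list to its 43794 widest peaks, the length of the shortest list on these chromosomes, was added after the data had been seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.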

Results

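ATAC-seq peak lists were compared between 4 genotypes of mouse lineage-negative HSPCs, the bone marrow fraction that holds stem and progenitor cells. Npm1c is a knock-in of a frameshift mutation of the nucleolar protein nucleophosmin that is recurrent in acute myeloid leukaemia, and it was recombined with Mx1-Cre, a Cre driven by an interferon-inducible promoter. Flt3-ITD is an internal tandem duplication of the cytokine receptor FLT3 that makes its signalling constitutive, and DM carries both alleles. Per the labels, the Npm1c and DM libraries carry Mx1-Cre and no Cre is named for the other 4, so a change given for the Npm1c allele is one of the allele together with Mx1-Cre. WT libraries held 80916 and 63908 peaks, Npm1c libraries 62782 and 68676, Flt3-ITD libraries 43825 and 51733, and DM libraries 55624 and 63133. The peaks covered 50.2 and 39.8 Mb in WT, 39.6 and 43.2 Mb in Npm1c, 24.2 and 29.8 Mb in Flt3-ITD and 30.0 and 33.9 Mb in DM. Of the 103446 merged regions, 26169 (25.3%) were called in all 8 libraries and 19140 in 1 library only, 59.6% lay inside a gene and 14.6% within 1 kb of a gene end. The labels call the replicates biological without naming the animals, so tests over libraries measure only the spread between these samples. The p-values of region counts, gene lists and runs come from reassigned calls or random gene lists. They do not measure the spread between libraries or animals.

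Libraries of the same genotype resembled each other more than libraries of different genotypes did. The mean Jaccard index of the 4 same-genotype pairs was 0.747 (range 0.722 to 0.783), against 0.520 (range 0.408 to 0.675) for pairs of different genotypes, and no other pairing of the 8 libraries reached it (next highest 0.704, exact permutation p = 0.00952, one-sided, the smallest this design can give). WT and Npm1c libraries shared most, with a mean index of 0.660, followed by Flt3-ITD and DM at 0.578 and WT and Flt3-ITD at 0.531. Lower values were those of Npm1c with Flt3-ITD, 0.489, WT with DM, 0.446, and Npm1c with DM, 0.417. The index of a pair cannot exceed the ratio of the shorter to the longer covered length. Pairs of a short Flt3-ITD list with a longer WT or Npm1c list are thus held low, and this order mixes list length with likeness.

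**Figure D1:**
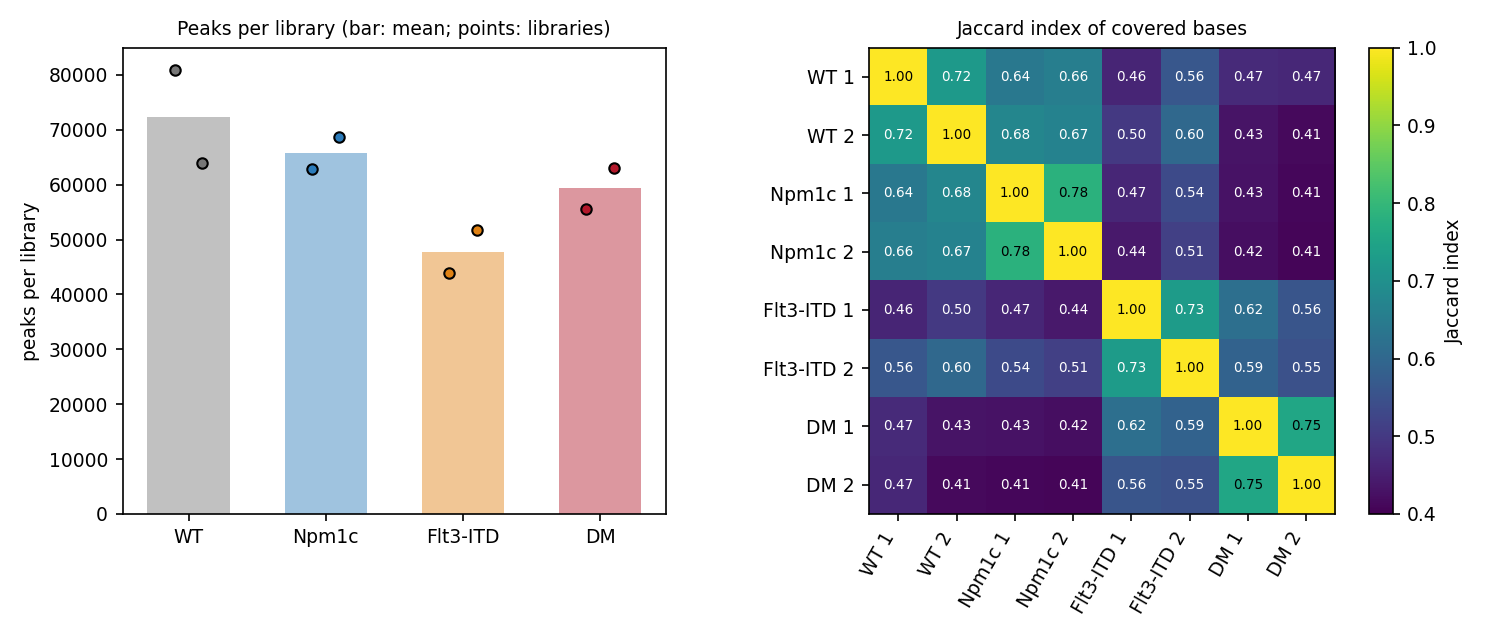
Peaks per library by genotype (left, number of peaks, bars for the mean of 2 libraries and points for libraries) and the Jaccard index of covered bases for every pair of libraries (right, colour from 0.4 to 1). The Flt3-ITD libraries hold 43825 and 51733 peaks, the fewest of the 4 genotypes, and the lowest mean index, 0.417, is that of Npm1c with DM.

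The lists of libraries with the Flt3-ITD allele were shorter, with a mean of 53579 ± 8042 peaks (SD, n = 4) against 69071 ± 8300 without it (n = 4). The exact permutation test gave a two-sided p of 0.0571 (adjusted p = 0.137 over 12 comparisons), and between 0.0286 (without DM replicate 2) and 0.114 (without Flt3-ITD replicate 1) with single libraries left out. Covered length was 29.5 ± 3.98 Mb with the allele and 43.2 ± 4.96 Mb without it (n = 4 each, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0857). Libraries with the Npm1c allele held 62554 ± 5351 peaks and those without it 60096 ± 16152 (n = 4 each, exact permutation p = 0.857). A shorter list turns calls into absences across the genome. Total losses against WT in the libraries with Flt3-ITD are thus given below beside the values from lists of equal length, which draw gained and lost counts together by construction. Losses at single genes and the tests for fewer lost regions have no such value.

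The 3 genes fixed in advance for every library were Npm1, Flt3 and Mx1. A region at Npm1 (11:33161942-33163746), inside the gene, was called in all 8 libraries. The other regions of Npm1, at 11:33170496-33170899 and 11:33176584-33176916, with midpoints 6555 and 12608 bp beyond the gene, were called in all 4 libraries without the Flt3-ITD allele and in none of the 4 with it. Inside Flt3, the region at 5:147351530-147352314 had the opposite pattern, called in all 4 libraries with the allele and in none without it, while 7 of the 18 regions of Flt3 were called in all 8 libraries. Flt3 held 10 and 9 called regions in WT, 11 and 10 in Npm1c, 10 and 9 in Flt3-ITD and 10 and 16 in DM. At Mx1, an interferon-induced GTPase, the regions 16:97463456-97463966 and 16:97466593-97466942, with midpoints 805 and 3861 bp from the gene, were called in all 4 Npm1c and DM libraries, which per the labels carry Mx1-Cre, and in none of the other 4. Mx1 held 1 and 0 called regions in WT, 4 and 3 in Npm1c, 1 and 1 in Flt3-ITD and 3 and 4 in DM. It is 1 of 6 genes with at least 2 regions of this pattern, and Tet2, named here after its values were seen, had 4. A 4 against 4 pattern at a single region has a Fisher exact p of 0.0286 and an adjusted p of 0.320 for the Flt3-ITD allele and 1 for the Npm1c allele, so none of these regions passes on its own. Peak positions do not read the mutated alleles and cannot check the genotypes.

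The comparison of Npm1c with WT asks what this allele, together with Mx1-Cre, changes without Flt3-ITD. In Npm1c HSPCs 2799 regions (2.71% of all regions) were gained and 6480 (6.26%) lost. Heat shock genes held 3 of the 5 widest gained regions, at Hsph1 (5:149614659-149619378, 4720 bp), Dnajb4 (3:152182790-152184758, inside the gene) and Hspa1a (17:34968018-34970039, overlapping one end of the gene), chaperones or co-chaperones of protein folding, and another lay inside Rab3gap2. Lsamp, a neuronal adhesion molecule, had most gained regions (8 of 16), followed by Samsn1 (7 of 34), Thsd7b (7 of 29), Plcb1 (6 of 25) and Tet2 (6 of 23), a DNA demethylase mutated in myeloid neoplasia. Gse1 had most lost regions (17 of 100), followed by Arid1b (15 of 65), a subunit of the BAF chromatin remodelling complex, Mdga1 (12 of 29), Septin9 (11 of 51) and Ksr1 (10 of 38), and the widest lost regions lay inside Nags, Bsn, Hcn3, Cplx2 and Phospho1. At most 5 gained regions fell within 20 kb, at Hsph1 and at a locus on chromosome 6 (at most 5 in calls reassigned to random regions, permutation p = 0.00799). Of lost regions, at most 6 did, at Yjefn3 and at a locus on chromosome 17 (at most 6, permutation p = 0.0170). These are 2 of 8 such tests, added after the data had been seen and not adjusted.

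Among the gene lists, no excess passed in Npm1c against WT, with a lowest adjusted permutation p of 0.887 over 32 tests and no test with an unadjusted p under 0.05. The HOX cluster and cofactor list, whose genes are highly expressed in NPM1-mutant leukaemia, had 4 gained regions against a random mean of 3.10, 1 each at Hoxa9, Hoxa10, Meis1 and Meis2. The same list also lost regions, among them 6 at Mn1, 2 at Meis1 and 1 each at Pbx3 and Hoxb8. The stem cell list had 11 gained regions (random mean 7.48), 5 of them at Cd34, and the erythroid list 13 (7.09), at Sox6 (4), Car1 (3), Car2 (3) and others. The interferon response list had 7 (3.15), including Ifih1 (2) and Mx1 (2), and the B-lymphoid list 5, all at Bank1. Lost regions included 9 at Runx3, 7 at Runx1, 6 each at Zfpm1, Mn1 and Ly86, and 5 of the 8 regions of Tcf7. The stem cell, erythroid and B-lymphoid lists thus lost regions too, for example at Runx1, Zfpm1 and Dntt (2). Both counts exceeded the randomisation (means 1816 and 4262, permutation p = 0.001 each, the smallest possible), which likeness of replicates alone can give. The gained count barely exceeded the highest mixed split of these 4 libraries, 2782. It was 7744 without WT replicate 1 and 6402 without Npm1c replicate 1, and the lost count was 17926 without WT replicate 2 and 3652 with lists of equal length.

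The comparison of Flt3-ITD with WT asks the same of the receptor mutation. Few regions were gained, 881 (0.852% of all regions), and 16751 (16.2%) were lost. Mroh2a had most gained regions (14 of 25), and 13 of them fell within 20 kb (1:88228383-88246100, midpoints), where reassigning the gained calls to random regions gave at most 4 in any such window (permutation p = 0.001, the smallest possible). Peaks covered 62.9% and 53.0% of Mroh2a in the Flt3-ITD libraries, 26.6% and 24.4% in WT and 6.78% and 4.97% in DM. Grm4 gained 5 regions, one of them among the widest (17:27374974-27376247), and Irf8, the transcription factor of monocyte and dendritic cell fate, Xxylt1 and Srcin1 gained 4 each, and the widest gains outside these genes were at Ypel2 and Sec14l5. Most losses were at St6galnac3 (21 of 66), Sox5 (21 of 60), Arid1b (19 of 65), Etv6 (18 of 75) and Foxp1 (18 of 97), and the widest lost regions lay at Aqp1, Denn2b, Uap1, Aff1 and Foxn3. The most lost regions within 20 kb were 7, at Synpo2, where reassigned calls reached 11 (permutation p = 0.338).

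No list had an excess of gained or lost regions in Flt3-ITD against WT at an adjusted permutation p under 0.05. The lowest was that of the monocyte and macrophage list, with 9 gained regions against a random mean of 2.25 (unadjusted permutation p = 0.005, adjusted p = 0.160), at Irf8 (4), Ly6c2 (2), Cebpb, F13a1 and another gene. The megakaryocyte list had 6 gained regions (1.75, adjusted permutation p = 0.363), at Tubb1, Ppbp, Gp6, Cd9 and others, and the AP-1 list 5 (1.61, adjusted p = 0.415), at Klf6, Nr4a1, Fos, Fosl2 and another gene. Fewer regions than in random lists were lost in 5 lists, a test added after the data had been seen and not rerun with equal list lengths. These were JAK-STAT and FLT3 signalling (39 of 437 regions against 73.3, adjusted permutation p = 0.0128), monocyte and macrophage (26 against 47.8, 0.0288), AP-1 (13 against 29.5, 0.0288), dendritic (15 against 30.1, 0.0454) and neutrophil granule (8 against 19.1, 0.0454). Random lists were not matched on peak width, and the part of list length in these values was not tested. Zeb2 lost 15 of 44 regions, Bcl11a 10 of 45, Mef2c 10 of 39, Tcf4 9 of 36, Sox6 8 of 36 and Bcl2 8 of 34. Prdm16 lost 7 of 24, Meis1 7 of 31, Erg 7 of 40 and Runx1 7 of 56, the last below the 16.2% of all regions. Both counts exceeded the randomisation (means 342 and 10957, permutation p = 0.001 each), but the gained count lay below the highest mixed split, 1505. With lists of equal length the counts were 4238 and 4704, and single libraries moved the gained count to 4781 (without WT replicate 1), 1647 (without Flt3-ITD replicate 1) and 1385 (without Flt3-ITD replicate 2) and the lost count to 30682 (without WT replicate 2).

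**Figure D2:**
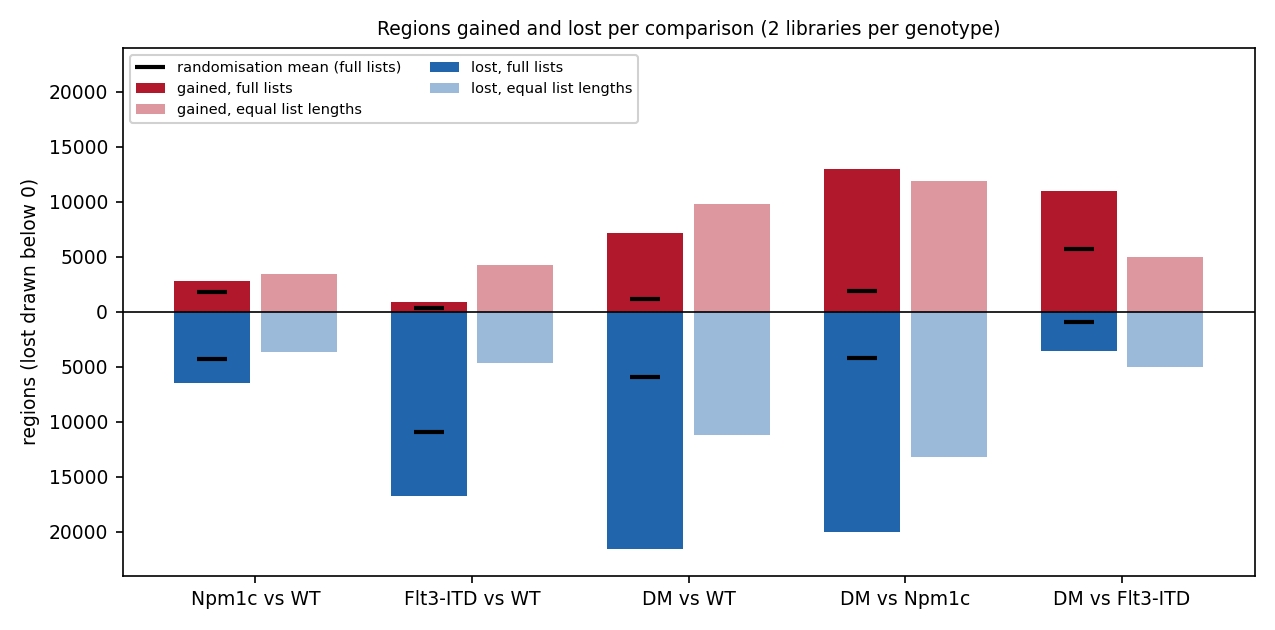
Regions gained (above 0) and lost (below 0) in each comparison of 2 libraries with 2 libraries, with the full lists (dark bars), with every list reduced to its 43794 widest peaks (light bars) and with the mean of the randomisation (black lines). In Flt3-ITD against WT, 881 gained and 16751 lost regions became 4238 and 4704 with equal list lengths, and in DM against WT 7164 and 21591 became 9836 and 11183.

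The comparison of DM with WT asks what both alleles and Mx1-Cre change together. In DM, 7164 regions (6.93% of all regions) were gained and 21591 (20.9%) lost. Irf8 gained 22 of its 48 regions, more than any other gene, and 12 of them fell within 20 kb (8:120739459-120757428, midpoints), where reassigned calls gave at most 8 (permutation p = 0.001, the smallest possible). Peaks covered 35.96% and 64.4% of Irf8 in the DM libraries and between 0.742% and 5.87% in the other 6. The widest gained region overlapped one end of Cd74 (18:60810518-60814824, 4307 bp), the invariant chain of MHC class II, and the other wide gains lay at Lrpap1, Hspa1a, Hemk1 and Grm4. Gains were also frequent at Zfp469 (13 of 32), Cradd (10 of 40), Prex1 (10 of 57), a Rac exchange factor of myeloid cells, and Tle3 (9 of 35). By number, losses were most frequent at Gse1 (25 of 100, near the 20.9% of all regions), St6galnac3 (25 of 66), Sox5 (23 of 60), Arid1b (23 of 65) and Nfia (22 of 61). The widest lost regions lay at Vps13d (4:145032284-145035988), Gse1, Gja1, Myl9 and Uckl1. The most lost regions within 20 kb were 8, at Ntn4, where reassigned calls reached 12 (permutation p = 0.288).

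Genes of the dendritic list gained regions in DM and those of the erythroid list lost them, while an excess of gains in the monocyte and macrophage list rested on Irf8. The monocyte and macrophage list gained 50 of its 278 regions against 18.3 in random lists (adjusted permutation p = 0.00960), at Irf8 (22), F13a1 (6), the transcription factor Cebpb (4), the Fc receptor Fcgr1 (3) and 9 other genes. Without Irf8, 28 were gained (adjusted permutation p = 0.228), and with all its genes 84 were gained without DM replicate 1 and 91 without WT replicate 1. The dendritic list gained 34 of 205 (12.96, adjusted p = 0.00640 by permutation) at 14 of its 20 genes with a region, including Runx2 (7), the MHC class II transactivator Ciita (5), Cd74 (3) and Tcf4 (3), with 3 of them within 1 kb of a gene end (adjusted p = 0.145). It gained 65 without DM replicate 1 and 66 without WT replicate 1. Of the genes named, Tcf4 lost more regions than it gained, 6 of 36. The T and NK list gained 23 of 148 (10.3, adjusted permutation p = 0.0320), at Bcl11b (4), Il2rb, Cd2 and Cd6 (3 each) and others. That excess ended at a gene distance of 50 kb (adjusted permutation p = 0.0680), with equal list lengths (0.382) and without WT replicate 1 (36 regions, 0.117), and 39 were gained without DM replicate 1. Cd2 also lost 3 of its 13 regions. The erythroid list lost 102 of 294 regions (64.9, adjusted permutation p = 0.0107) at 23 of its 28 genes with a region, among them Bcl11a (14), the GATA1 cofactor Zfpm1 (14), Sox6 (11) and the carbonic anhydrase gene Car2 (10). It lost 63 with equal list lengths (adjusted permutation p = 0.0112).

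In the same comparison 6 lists lost fewer regions than random lists, by the test added after the data had been seen. That test was not rerun with equal list lengths, and its random lists were not matched on peak width. The dendritic list lost 11 (39.3 in random lists, adjusted permutation p = 0.00320), the neutrophil granule list 8 (24.8, 0.00480), the AP-1 list 15 (38.5, 0.00533), the monocyte and macrophage list 31 (62.8, 0.00640), 21 of them at Zeb2, the JAK-STAT list 60 (96.1, 0.0141) and the B-lymphoid list 21 (41.5, 0.0213). No other excess passed an adjusted permutation p of 0.05. The neutrophil granule list gained 13 regions (7.86), with Cebpa (3), Csf3r, Mpo and Itgam (2 each), the JAK-STAT list gained 43 (32.2), with Socs2 (7 of 14), Ccnd1 (4) and Dusp5 (4), and the AP-1 list 15 (12.7), with Maff, Nr4a1 and Fos (3 each). HOX genes gained 8 (8.16), stem cell genes 16 (22.0), megakaryocyte genes 12 (13.7), B-lymphoid genes 20 (12.7), mast cell and basophil genes 3 (7.503), stroma and endothelium genes 10 (9.94), interferon response genes 8 (7.77), transcription factor genes 70 (54.0) and housekeeping genes 4 (7.71). Stem cell genes lost 83 (70.2), with Runx1 (12), Lmo2 (10), Fli1 (8) and Angpt1 (7), megakaryocyte genes 55 (41.9, adjusted permutation p = 0.327), with Zfpm1 (14) and Vwf (7), and HOX genes 23 (25.8), including 6 at Meis1. The gained and lost counts exceeded the randomisation (means 1150 and 5908, permutation p = 0.001 each), which likeness of replicates alone can give, and the highest mixed split, 1501. With equal list lengths 11183 regions were lost, and the gained count was 16210 without WT replicate 1 and 14540 without DM replicate 1.

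**Figure D3:**
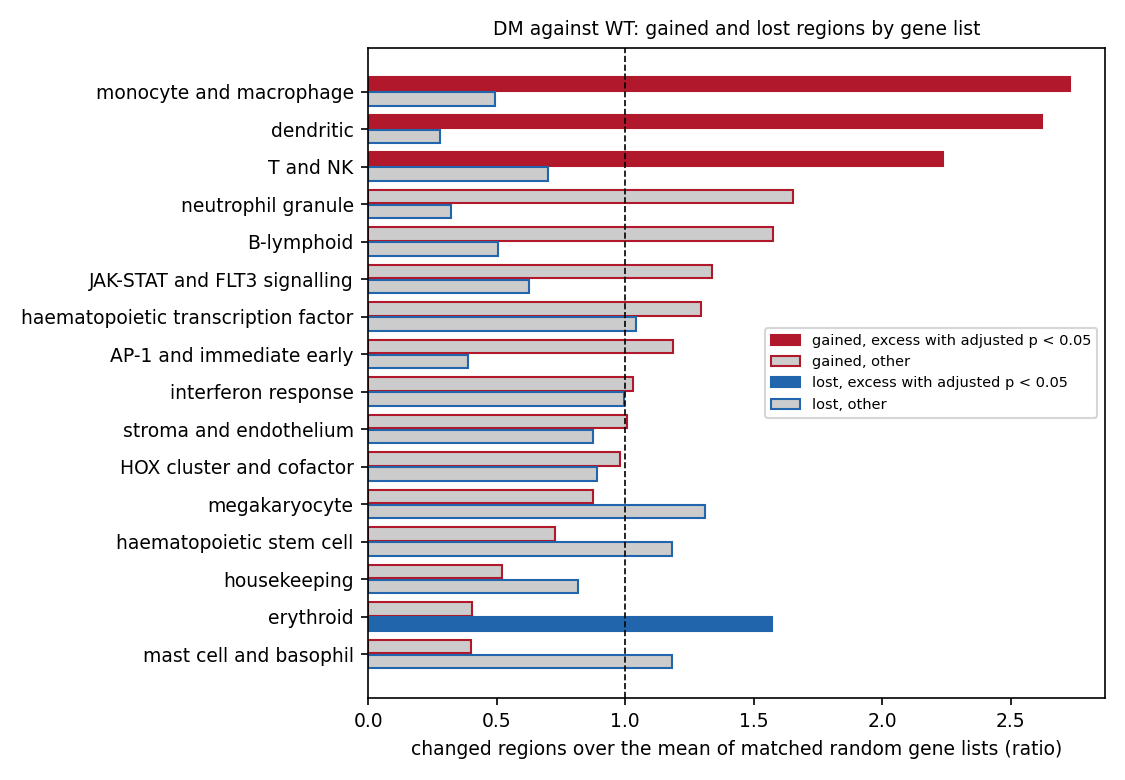
Gained and lost regions of DM against WT in each gene list, as the ratio of the observed number to the mean of 10000 matched random gene lists (dashed line at 1), with filled bars for an excess at an adjusted p under 0.05. The monocyte and macrophage list had 50 gained regions against 18.3, and the erythroid list 102 lost regions against 64.9.

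**Figure D4:**
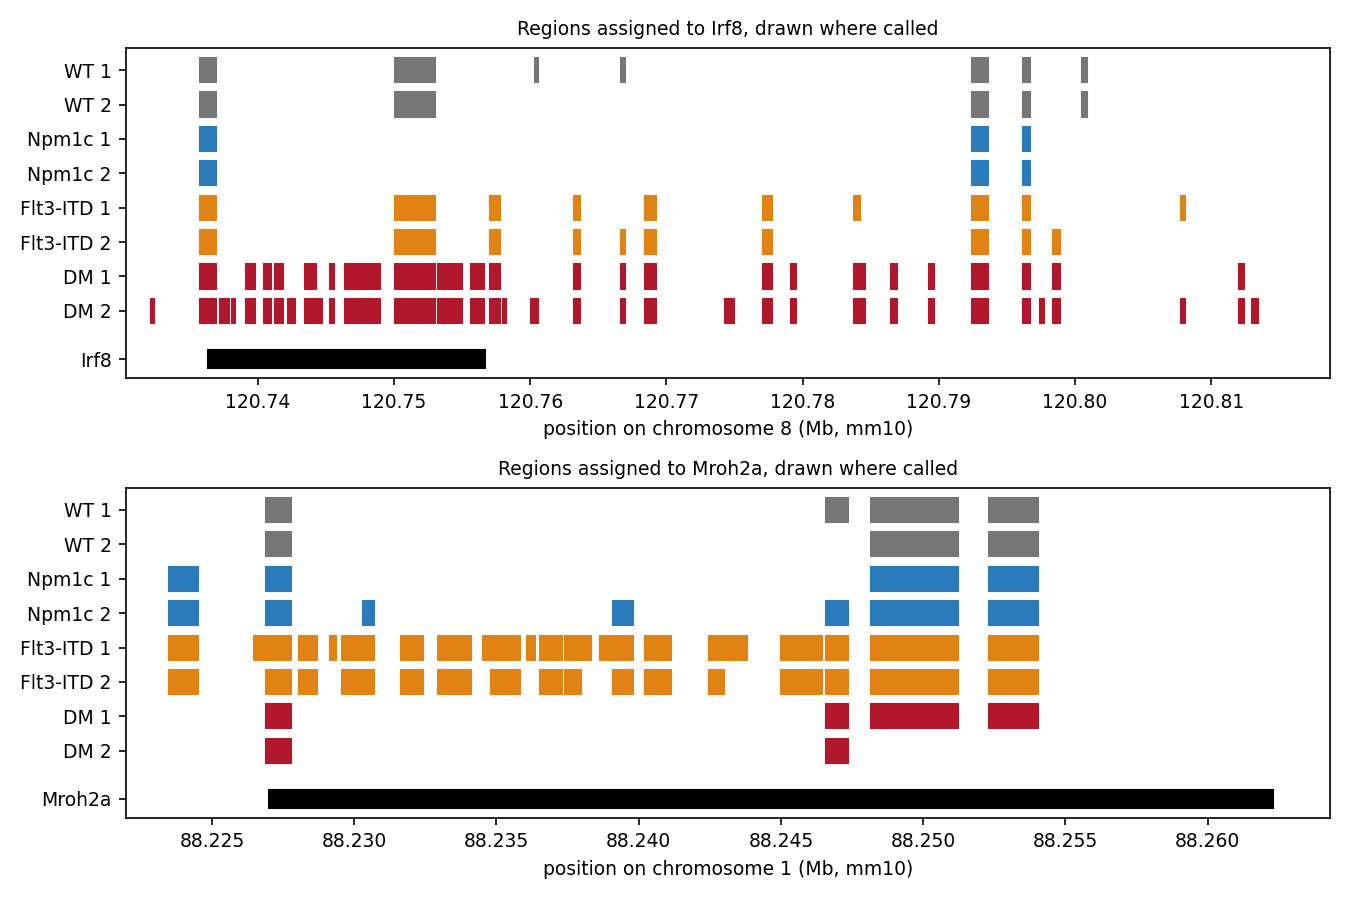
Regions called in each of the 8 libraries around Irf8 (top, chromosome 8) and Mroh2a (bottom, chromosome 1), by position in Mb on mm10, with the gene as a black bar. Peaks cover 35.96% and 64.4% of Irf8 in the DM libraries, and 62.9% and 53.0% of Mroh2a in the Flt3-ITD libraries.

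Setting DM against Npm1c asks what the Flt3-ITD allele adds where Npm1c is already present. Here 12992 regions (12.6% of all regions) were gained and 19986 (19.3%) lost. Irf8 gained 27 regions, Prex1 21, Gse1 and Septin9 18 each and Zfp469 17, and the widest gains lay at Cd74, Rab11fip4, Grik4, Hdac5 and Trmt61a. Nfia lost 29 regions, Sox5 28, Pde4d 27, St6galnac3 25 and Zeb2 23, and the widest losses lay at the beta-globin gene Hbb-bt (7:103808341-103811916), Arpp21, Vps13d, Ttc27 and Car2. An excess of gains was found for the monocyte and macrophage list (80 against 35.1, adjusted permutation p = 0.00800), with Irf8, Ly86 (14), Cebpb (8) and F13a1 (6), the dendritic list (54 against 24.2, 0.00800), with Runx2 (11), Ccr7 (7) and Ciita (5), the neutrophil granule list (32 against 14.5, 0.0112), with Cebpa, Itgam and Padi4 (4 each), and the T and NK list (37 against 18.8, 0.0160), with Il2rb and Bcl11b (5 each). The erythroid list lost 104 regions (59.6, adjusted permutation p = 0.0112), with Sox6 (17), Car2 (14), Bcl11a (12) and Car1 (7 of 9), and it gained fewer than random lists, 13 against 37.9 (0.0448, test added later). Some of these calls ended under an alternative, the monocyte one without Irf8 (adjusted permutation p = 0.0781), the dendritic one within 1 kb of a gene end (0.103) and, with equal list lengths, those of the neutrophil (0.0544) and T and NK lists (0.229). Both region counts exceeded the randomisation (means 1922 and 4212, permutation p = 0.001 each) and the highest mixed split, 640, with 21537 gained without DM replicate 1 and 13195 lost with equal list lengths.

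Setting DM against Flt3-ITD asks what the Npm1c allele and Mx1-Cre, which cannot be told apart, add where Flt3-ITD is already present. Gains outnumbered losses, 11009 (10.6% of all regions) to 3560 (3.44%). Irf8 gained 17 regions, Nav2 14 and Wwox, Foxp1 and Maml3 13 each, and the widest gains lay at Cd74, Cdh2, Hspa1a, Irf8 and Cdh23. Mroh2a lost the same number that it had gained in Flt3-ITD, 14 of 25, Zfpm1 and Gse1 lost 9 each and Cmip and Chst1 7 each, and the widest losses lay at Abcg4, Zfp36l1, Mgat4e, Phyhip and Zfpm1. The dendritic list gained 45 regions (20.2 in random lists, adjusted permutation p = 0.00213), with Runx2 (9), Tcf4 and Ciita (6 each) and Batf3 (4), of which 3 lay within 1 kb of a gene end (0.375). It gained 24 with equal list lengths (adjusted permutation p = 0.00427). The megakaryocyte list lost 32 regions (7.20, adjusted permutation p = 0.00213), with Zfpm1 (9), Rab27b (4), Cd9 (3) and the platelet glycoprotein gene Gp9 (3 of 5), and the erythroid list also lost 32 (11.2, 0.00213), with Zfpm1, Ank1 (3), Rhd and Ermap (2 each). The erythroid list gained 12 regions, fewer than the 31.7 of random lists (adjusted permutation p = 0.0192, test added later). Both region counts exceeded the randomisation (means 5678 and 911, permutation p = 0.001 each) and the highest mixed split, 882. With equal list lengths 4935 regions were gained and 5046 lost, which equal lengths nearly balance by construction. Single libraries moved the counts to 20597 gained (without DM replicate 1) and 8540 lost (without Flt3-ITD replicate 1).

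Regions particular to DM were called in both DM libraries and in none of the other 6, which held for 5308, and 2872 were called in those 6 and in neither DM library. Irf8 had 16 of the DM-only regions, 11 of them within 20 kb (at most 7 in reassigned calls, permutation p = 0.001), Cradd 9, the histone variant gene Macroh2a1 9 of 16, Cdh13 8 of 12 and Tmem108 8, and the widest lay at Cd74, Irf8, Cdh23, Prss30 and Clec2f. Regions missing from DM only were most frequent at Pde4d, Cmip, Mtss1, Zfpm1 and Chst1 (6 each), and the widest lay at Vps13d, Mgat4e, Phyhip and Abcg4. At most 4 of them fell within 20 kb, at Slc25a44 and at another locus of chromosome 3 (6 in reassigned calls, permutation p = 0.208). In list tests added after the data had been seen, DM-only regions were in excess in the dendritic list (30 against 9.59, adjusted permutation p = 0.00160), with Runx2 (7), Ciita (5), Cd74 (3) and Batf3 (3), the monocyte and macrophage list (36 against 13.5, 0.0109) and the T and NK list (20 against 7.59, 0.0109), with Bcl11b, Cd2 and Cd6 (3 each). Regions missing from DM only were in excess in the erythroid list (29 against 9.10, adjusted permutation p = 0.00160) and the megakaryocyte list (19 against 5.78, 0.00213). With equal list lengths the monocyte, T and NK and megakaryocyte excesses ended (adjusted permutation p = 0.448 each), and the monocyte one also ended without Irf8 (0.242), while within 1 kb of a gene end the dendritic (0.0912), monocyte (0.124) and megakaryocyte (0.0912) excesses ended. The DM-only count was 12267 without DM replicate 1, and the count missing from DM only was 6301 without Flt3-ITD replicate 1 and 1877 where a call needed 50% of the region.

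Regions that followed an allele across both backgrounds were called in all 4 libraries with it and in none without it, or the reverse. For Flt3-ITD there were 9250, of which 585 were called with the allele and 8665 without it. St6galnac3 had 15 of those called without it, Zeb2 and Sox5 14 each, Nfia, Pde4d and Psd3 13 each, and Etv6 and Ikzf2 11 each, and the widest lay at Zeb2, Uap1, Aqp1, Foxn3 and Aff1. Of those called with it, Grm4, Irf8 and Srcin1 had 4 each, Lrpap1 3 and Glp1r 3 of 4. The JAK-STAT list had 15 of the regions called without the allele, fewer than the 38.7 of random lists (adjusted permutation p = 0.0416, test added later and not rerun with equal list lengths). Npm1c was followed by 372 regions, 161 called with the allele and 211 without it. Among the 161 were 4 regions at Tet2, the Hspa1a region named above, a region inside Hoxa10 (6:52231895-52233221), 2 at Mx1 and 1 each at Tcf4 and Il2ra, and the megakaryocyte list had 5 of the 211 (0.377 in random lists, adjusted permutation p = 0.0128), at Gp9 (2), Gp1bb, Vwf and Zfpm1, an excess that ended with equal list lengths (0.0960) and within 1 kb of a gene end (0.125). Fisher exact tests of single regions left 0 of them below an adjusted p of 0.05 for either allele (smallest adjusted p 0.320 for Flt3-ITD and 1 for Npm1c), with 9250 and 372 regions at an unadjusted p under 0.05. With equal list lengths the Flt3-ITD count was 5717, of which 2896 were called with the allele and 2821 without it, and since equal lengths draw these together, they do not show which of them prevails. The Npm1c count was 648 there, 192 called with the allele and 456 without it, and it was 1509 without WT replicate 1, 1046 without Flt3-ITD replicate 1 and 679 without Npm1c replicate 1.

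Most changes of Flt3-ITD HSPCs against WT were also present in DM. Of the 881 regions gained in Flt3-ITD, 619 (70.3%) were gained in DM too, against 82.3 in the randomisation, which shares the WT libraries, and 61.0 for independent lists (permutation p = 0.001). Of the 16751 lost, 13701 (81.8%) were lost in DM (3539 and 3496, permutation p = 0.001). Gains of Npm1c were rarely found in DM, 188 of 2799 (6.72%), below the 326 of the randomisation and near the 194 of independent lists, and 23 were shared with Flt3-ITD (113 and 23.8). Losses of Npm1c were shared with DM at 4060 regions (1894 and 1352) and with Flt3-ITD at 3618 (2699 and 1049, permutation p = 0.001 each). In all, 796 regions were gained and 15127 lost in at least 2 mutant genotypes, 3832 and 5282 with equal list lengths, and the 3 genotypes shared 17 gains and 3126 losses. Part of each excess may come from the shared WT libraries. Part of the losses shared by Flt3-ITD and DM may also come from list length. Peaks of every Flt3-ITD and DM library covered less of the genome than those of any WT or Npm1c library. The overlap of Flt3-ITD with DM is given for the full lists only. How many of the 13701 shared losses come from list length thus stays open.

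Whether the effect of an allele differed with the other allele present was tested over 36 arrangements of the libraries, in a test added after the data had been seen whose smallest exact permutation p is 0.0556. The Flt3-ITD allele gained 12111 more regions in the presence of Npm1c than in its absence (exact p = 0.0556) and lost 3235 more (exact p = 0.667). The Npm1c allele gained 8210 more regions in the presence of Flt3-ITD (exact permutation p = 0.111), and for losses the difference was -2920 (exact permutation p = 0.444). These differences depend on list length. With equal list lengths those of the Flt3-ITD allele were 7691 gained and 8491 lost (exact permutation p = 0.0556 each), and those of the Npm1c allele 1518 gained (exact permutation p = 0.167) and 1394 lost (0.222), the last with the opposite sign. No test here can pass 0.05.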

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

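Apart from the counts over the 35 splits of the libraries and the test of peak width, the tests in this part were chosen after the data had been seen. Within-genotype spread rests on 2 libraries.

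Of 32 comparisons of list shares between backgrounds, 3 had effects of opposite sign in every library, where chance gives 5.56%, or 1.78 of them. The differences were not tested. The share of called regions assigned to megakaryocyte genes was 0.221% in WT, 0.224% in Npm1c, 0.264% in Flt3-ITD and 0.173% in DM, so the effect of the Flt3-ITD allele was 0.0431 points without Npm1c and -0.0506 with it, a difference of -0.0937. For T and NK genes, the effect of the Npm1c allele was -0.0197 points without Flt3-ITD and 0.0336 with it, a difference of 0.0533. For stroma and endothelium genes these effects were -0.0122 and 0.0234, a difference of 0.0357. Outside the chromosomes compared, a mean of 45.5 peaks per library lay on unplaced sequences in Npm1c and 25.5 in WT, which was not tested. In 12 tests for a library far from the others of its allele group, 0 met the criterion.

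For the 9250 regions split by the Flt3-ITD allele, chance can be excluded for groupings that ignore genotype, since 1 of the 35 splits of the 8 libraries into equal groups, the real one, gave as many and the highest of the others gave 599. Libraries of a genotype resemble each other, however, and the splits that keep genotypes whole (9250, 372 and 222 regions) are too few for a share under 0.05. Chance cannot be excluded for the 372 regions split by the Npm1c allele, since 4 of the 35 gave as many, the highest being the split by Flt3-ITD with 9250. The next, with 599 and 597 regions, part the libraries of a genotype and put WT replicate 1, the longest list, with both DM libraries. The splits that set 1 genotype against the other 3, of which there are 4, are too few for a share under 0.05. Among them 1, the real one, reached the 5308 regions called only in DM (highest other 3126, the WT pair) and 1 the 2872 missing only from DM (highest other 1242, the Npm1c pair), a comparison that replaced one over all 28 pairs of libraries after it had been seen.

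Regions missing from libraries with the Flt3-ITD allele may come from shorter peak lists or from a change of chromatin with the allele. Of these regions, 21.5% had a peak wider than the median peak in WT replicate 2, between the limits of 10% and 25% written before the result was seen, so this measure leaves shorter lists open (a first test on 1 pair of libraries was dropped after it was seen, since 1 pair excludes nothing). Lists of equal length argue only against the number of peaks as the whole cause. With them 2821 regions were still missing with the allele, against 456 at most in either direction of other splits. DM against WT still lost 11183 against 388 at most for mixed splits. Mixed splits and most other splits part the libraries of a genotype, whose likeness from any source widens these gaps. Equal lengths do not equalise read depth or signal, which are unknown, so a technical cause beyond list length stays open. The number missing fell from 8665 to 2821 there, beside 2896 called only with the allele, but equal lengths draw these counts together by construction, so their balance decides nothing. How many of the losses come from list length stays open, and a change in the mix of cell types, a biological difference, was not tested.

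Gained regions of heat shock genes in the Npm1c libraries were noticed first among the widest gains. The list of 20 such genes was written after that, so its 20 gained regions (2.90 in random lists) are not independent evidence. Random placement stays open for the set, since among the 9 genes not looked at before 3 of 30 regions were gained (0.800, permutation p = 0.067). A run of 5 gained regions within 20 kb at Hsph1 (unadjusted permutation p = 0.00799) does not decide it. Hsph1 is 1 of the genes that prompted the list, reassigned calls also reached 5, and a locus on chromosome 6 had as many. Against the Npm1c allele whatever the Flt3 genotype, DM gained 4 regions of the list against Flt3-ITD, fewer than the 11.1 of random lists (lower-tail permutation p = 0.0254). This explanation stays open, since the Hspa1a region was called in all 4 libraries with Npm1c and in none without it (1 region against 0.163 in random lists). DM also lost 39 regions of the list against Npm1c (21.1, permutation p = 0.00540). The list was chosen from gains in those same Npm1c libraries, so these losses are not independent evidence and decide nothing. The test against Flt3-ITD replaced a first one, the difference of mean counts (-3 regions in DM against Flt3-ITD), after both had been seen. Heat or handling of these 2 libraries could raise immediate early genes as well, whose 6 gained regions lay within the range of random lists (mean 4.69), so handling and an effect of Npm1c or Mx1-Cre cannot be told apart.

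Regions beside Mx1 in the libraries with Mx1-Cre may come from copies of the Mx1 promoter in the transgene, from an interferon response or from random placement. Random placement stays open, since 6 genes, Mx1 included, had at least the 2 regions of Mx1 with the pattern, out of 140 over all genes, and Tet2 had 4. For an interferon response, 0 regions of the 26 other interferon response genes with a region had it, but random lists had 0.169 on average, so the test has no power. For copies of the Mx1 promoter, the 2 regions lie on one side of the gene, which a change of the gene itself would give too, and Mx1-Cre and the Npm1c allele are present in the same libraries and cannot be told apart.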

How the results depend on the processing

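The alternatives with equal list lengths, the wider 50% of each list, regions within 1 kb of a gene end, lists without Irf8 and gene lists without single libraries were chosen after the data had been seen. Of 299 alternatives, 226 kept the direction and the side of the threshold, or a count within 1.5 times, and 73 did not. All 10 counts with the replicate number as a replicate block were equal to the main ones by construction, such as 2799 regions gained in Npm1c, and correlations between libraries with the same number (-0.0399 to 0.0387) show that they share only a number. Calls from the wider 50% of each list gave 1833 gained and 3491 lost in Npm1c against WT, 324 and 7546 in Flt3-ITD against WT, 3921 and 10778 in DM against WT, 6705 and 10250 in DM against Npm1c, 5639 and 1819 in DM against Flt3-ITD, 4124 split by the Flt3-ITD allele, 2938 only in DM, 1472 missing only from DM, and 372 gained and 7244 lost in at least 2 mutant genotypes, and the cause was not tested. Counting regions called in at least 1 library of one group relaxes the criterion by construction, to 7687 gained and 19104 lost in Npm1c, 2151 and 32818 in Flt3-ITD and 15919 and 32576 in DM, all against WT, and in DM to 23260 gained against Npm1c and 22948 gained and 8938 lost against Flt3-ITD. With equal list lengths 3652 regions were lost in Npm1c, 4238 gained and 4704 lost in Flt3-ITD, 11183 lost in DM, 13195 lost in DM against Npm1c, 4935 gained in DM against Flt3-ITD, 5717 and 648 split by the Flt3-ITD and Npm1c alleles, 3832 gained and 5282 lost in at least 2 mutant genotypes, and the difference in losses by Npm1c with against without Flt3-ITD was 1394 in place of -2920, and the cause was not tested beyond list length. There the erythroid list lost 63 regions in DM against WT, the dendritic list gained 24 against Flt3-ITD, and the list excesses that ended were 26 neutrophil granule and 27 T and NK regions gained against Npm1c, 20 T and NK regions gained against WT, 17 monocyte and 9 T and NK regions only in DM, 12 megakaryocyte regions missing only from DM and 5 missing with Npm1c. Within 1 kb of a gene end, those that ended were 3, 5, 3 and 3 dendritic regions gained against WT, Npm1c, Flt3-ITD and only in DM, 3 monocyte regions only in DM, 3 megakaryocyte regions missing only from DM and 2 with Npm1c, where fewer regions enter the test. Without Irf8 the monocyte counts were 28, 53 and 20 (against WT, Npm1c and only in DM), up to 50 kb 20 T and NK regions were gained against WT, and with 50% of a region covered 1877 were missing only from DM, of which the cause was not tested. Leaving out 1 library, which relaxes the criterion for regions by construction, gave 3477 to 7744 gained and 7658 to 17926 lost in Npm1c against WT, 917 to 4781 and 17448 to 30682 in Flt3-ITD against WT, 7210 to 16210 gained in DM against WT, 14040 to 21537 gained against Npm1c, 12339 to 20597 gained and 3958 to 8540 lost against Flt3-ITD, 431 to 1509 split by the Npm1c allele, 5317 to 12267 only in DM, 2874 to 6301 missing only from DM, 50 to 91 monocyte, 34 to 66 dendritic and 24 to 39 T and NK regions gained in DM against WT (36 T and NK regions without WT replicate 1, where the call ended), and a difference in peaks by the Flt3-ITD allele of -18663 to -11526. List excesses were rerun without single libraries for DM against WT only, and tests for fewer regions were not rerun under alternatives. Equal list length by score and a stricter score threshold were not run, since the lists hold no score, nor was a motif share, since no genome sequence was used. The depth behind each list is unknown, so an absent peak cannot be read as closed chromatin.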

Other observations

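The tests of list shares were chosen after the data had been seen, and the loci of this part were too. The Hoxa cluster (6:52155367-52260880), whose genes are highly expressed in stem cells and in NPM1-mutant leukaemia, held 24 regions, of which 15 and 10 were called in WT, 16 and 16 in Npm1c, 12 and 13 in Flt3-ITD and 15 and 18 in DM. Of these regions, 2 were gained in Npm1c and 2 in DM against WT, and 0 were lost in either. The Hoxb cluster (11:96271330-96368254) held 9, of which 7 and 7 were called in WT, 4 and 4 in Npm1c, 3 and 5 in Flt3-ITD and 3 and 5 in DM. Of these, 0 were gained in any of the 3 against WT, and 1 was lost in Npm1c, 1 in Flt3-ITD and 2 in DM.

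The share of called regions at 6 of the lists was higher in all 4 libraries with the Flt3-ITD allele than in all 4 without it, but in none of these 6 did a Flt3-ITD library hold more called regions than both WT libraries. JAK-STAT and FLT3 signalling genes held 0.525% ± 0.00895 (SD, n = 4) with the allele and 0.411% ± 0.0111 (n = 4) without it, AP-1 genes 0.219% and 0.162%, monocyte and macrophage genes 0.308% and 0.198%, dendritic genes 0.228% and 0.146%, neutrophil granule genes 0.137% and 0.0912%, and T and NK genes 0.141% and 0.108%. As numbers, JAK-STAT and FLT3 signalling genes held 331 and 244 called regions in WT, 244 and 260 in Npm1c, 213 and 245 in Flt3-ITD and 278 and 312 in DM, and monocyte and macrophage genes 169 and 115, 118 and 121, 119 and 124, and 173 and 205. In Flt3-ITD the higher share thus goes with fewer called regions elsewhere. Stem cell genes held a smaller share, 0.320% against 0.347%. Each has an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.131 over 32 tests, so none passes. The erythroid share was 0.235% with the allele and 0.322% without it (exact permutation p = 0.0571, adjusted p = 0.183).

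Of the peaks of a library on chromosomes 1 to 19 and X, chromosome 11 held a mean of 7.98% with the Flt3-ITD allele and 6.44% without it. Chromosome X held 1.68% and 2.27%, and peaks within 1 kb of a gene end made up 24.1% and 19.2% (n = 4 each, exact permutation p = 0.0286 and adjusted p = 0.0857 for each). Chromosome 11 was not particular in this. Chromosome 19 held 3.29% to 3.43% of peaks in libraries with the allele and 2.48% to 2.95% in those without it. For chromosome 3 the ranges were 4.44% to 4.75% and 5.26% to 5.94%, and neither was tested. By genotype, chromosome 11 held a mean of 6.99% in WT, 5.89% in Npm1c, 8.28% in Flt3-ITD and 7.68% in DM. Heat shock genes, a list written after the data had been seen, had 68 and 62 called regions in WT, 88 and 76 in Npm1c, 37 and 47 in Flt3-ITD and 40 and 38 in DM, and Hsph1 had 5 and 5, 15 and 11, 3 and 3, and 2 and 1 in the same order.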
